A study of Mus musculus with 2 samples.

How the data were processed

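Total RNA of mouse keratinocytes, the cells that make up most of the epidermis, was compared on 2 two-colour Agilent whole-genome gene expression arrays. Per the labels, each array carried RNA of wild-type keratinocytes in the Cy3 channel and RNA of keratinocytes deleted for Chuk through loxP sites, the sequences at which Cre recombinase cuts, in the Cy5 channel. The sample titles call the latter CHUK-LoxP mutant keratinocytes. The labels name no dye swap, so a dye effect and an effect of genotype cannot be told apart for any single probe. They number the arrays as replicates 1 and 2 of a single comparison and do not say whether the RNAs came from separate cultures or animals. The p-values therefore measure only the spread between these 2 arrays, which may be technical. Both arrays came from 1 slide and 1 scan, so neither of these separated them. The labels do not say whether culture, RNA extraction or labelling did.

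The deposited scanner output was written by Agilent Feature Extraction 9.1.3.1, per the file headers. The spot intensity in each channel is the mean pixel brightness, with the median brightness of the local background beside it, neither corrected nor dye normalised, per the file headers. The same files hold the software's processed intensity, which per the file headers was background subtracted, detrended and dye normalised by a linear and a LOWESS step within each array. They also hold a log10 ratio of processed Cy5 over Cy3 and, per the file headers, a p-value for that ratio from the software's error model within a single array. Other deposited columns are flags of 0 or 1 for spots well above background, saturated or outlying. The deposited value table of the series was set against the scanner values and equalled each array's log10 ratio column to within 0.005 in every spot, so its scale, direction and centring are those of the software. Both of its columns had a median of 0.

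Background was corrected in R 4.3.3 with limma 3.58.1 (normexp on the mean signals and median local backgrounds, offset 50), with data.table (version 1.17.8) for the tables. Log2 ratios of Cy5 over Cy3 were normalised by loess within each array, with control spots at weight 0 there and left out afterwards. Outlier spots were left out, 51 on array 1 and 18 on array 2. Spots of a probe were averaged. Of 41174 probes, 23519 were well above background in at least 1 channel on both arrays and were tested with lmFit and eBayes as the mean log2 ratio over the arrays against 0, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Each probe had 1 residual degree of freedom, to which eBayes added 5.20 prior degrees of freedom. In addition, genes were counted that lay at least 2-fold apart on both arrays in the same direction, a count that does not use the estimate of spread.

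Probe names were updated with a table of mouse RefSeq genes (GRCm38.p6), used for names and for the order of genes along chromosomes only. Of the tested probes, 16129 were named through an accession, 4721 through a symbol or synonym and 628 kept the name in the files, while 2041 had no gene name. A gene was represented by its tested probe with the highest mean log2 intensity, which gave 13739 genes. Of these, 5527 had several tested probes, and in 542 the probes were called in opposite directions. A gene whose probe was not well above background in one channel on both arrays has only a bound there. Its change is given as at least N-fold, from the bright channel's mean against the higher of the dim signal and the lowest signal well above background, per channel after loess and Aquantile. Such bounds are open to dye bias without a dye swap. They applied to 158 called genes. The probes of 8 tested genes had a saturated spot, and none of these was among the genes named by the rule below.

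Before the data were examined, 40 lists of genes were fixed from general knowledge of skin and of the study's subject. They cover keratinocyte layers and programs, signalling pathways, stress and handling responses, and markers of other cell types a skin culture could hold. They hold 734 genes, of which 616 were tested. The 35 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists. Camera with an estimated correlation, fry, and the rank of each list's median among 10000 random lists matched on mean intensity were alternatives. With 2 arrays, camera at an estimated correlation has 1 residual degree of freedom, so hardly any list can pass it. The rule for named genes, also fixed then, took Chuk, the 12 genes with the largest mean rise and the 12 with the largest mean fall among those past the threshold with the same direction on both arrays, and from each list up to 4 members past the threshold with the largest change, or the 2 brightest where none passed. The values of some genes that the rule names are not reported here. RIKEN clones, predicted genes and names that are only accessions were left out. Other genes are named where 5 or fewer members of a list went one way, or because they are widely used markers, and these were chosen after their values were seen.

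Alternatives planned before the data were examined changed the background correction, the normalisation, the filter on dim probes, the outlier flags, the rule for a gene's probe, the prior variance, the threshold and the list test, used the software's ratio or the value table, or left out an array. Scaling to the spike-in controls, limma's treat against a 1.5-fold change, and median centring with each array's median over all tested probes or all tested genes then set to that under loess were added after the data were seen. The fit was tested on simulated data: 200 of 23519 probes were changed in 2 simulated arrays of the Chuk comparison. It recovered 89% of changes of 0.5 and 100% of changes of 1 on the log2 scale, called 9 unchanged probes and gave 0 calls of the wrong sign. That simulation had no dye bias and drew its spread from the fitted prior, while 61.5% of the real probes passed the threshold. Its rates therefore do not carry over to the real calls. In a separate simulation of independent genes, camera passed a list shifted by 0.5 and did not pass an unshifted one. The number of arrays limits the precision of every value.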

Results

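Gene expression was measured on 2 two-colour arrays, each of which set RNA of keratinocytes labelled Chuk-deleted (Cy5) against RNA of wild-type keratinocytes (Cy3). The arrays form a single group of 2 replicates. Each carried 41174 gene probes. The median spot intensity was 109.9 in Cy3 and 218 in Cy5 on array 1, over local backgrounds of 42 and 74. On array 2 it was 95.2 and 171.5, over backgrounds of 41 and 72. On array 1, 59.1% of gene spots were well above background in Cy3 and 64.5% in Cy5, and on array 2 these shares were 53.2% and 57.4%. Values are mean log2 ratios of Cy5 over Cy3 with the SD of the 2 arrays (n = 2), and fold changes are those of the mean. Rose and fell stand for a signal that was higher or lower in the channel labelled Chuk-deleted and past the threshold of the limma fit.

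The comparison asks which transcripts change when keratinocytes lose Chuk, the gene of IKKα, a kinase of the IκB kinase complex whose loss blocks the maturation of the epidermis. The series title ties this gene to the upkeep of skin and to skin cancer. Chuk itself was measured by 2 probes, and both were higher in the channel labelled Chuk-deleted on both arrays. Probe A_51_P223475 gave log2 ratios of 0.73 and 0.75 (mean 0.74 ± 0.02, 1.67-fold, adjusted p = 9.57e-05, limma with Benjamini-Hochberg adjustment). Probe A_52_P386468 gave 0.93 and 0.78 (mean 0.85 ± 0.11, 1.81-fold, adjusted p = 9.69e-05 in the same fit). This goes against the label. Neither the labels nor the files give the deleted part of the gene or the place of the probes in it, and a probe outside the deleted part checks nothing. Every direction reported here therefore rests on the labels of the channels alone, and so does the deletion of Chuk. After each array was lowered by the mean ratio of its spike-in controls, the first probe lay at -0.02 (adjusted p = 0.881, limma).

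Genes of keratinocyte differentiation, of cell junctions and of the skin barrier were lower in the channel labelled Chuk-deleted, and basal keratinocyte genes and fibroblast marker genes were higher. These shifts of gene lists passed camera's threshold at a preset correlation and not at an estimated one (adjusted p from 0.698 to 0.731). At an estimated correlation 2 arrays leave the test 1 residual degree of freedom, so not passing it does not decide whether a list shifted. The estimated correlations lay above the preset 0.01 for the early suprabasal (0.44), late cornification (0.28), junction (0.35), barrier lipid (0.27), basal (0.27) and fibroblast (1) lists. From 2 arrays these estimates are imprecise. Where genes of a list do vary together, the p-values at the preset correlation are too small. After lowering by the spike-in mean the medians of the basal and fibroblast lists were 0.07 and 0.01. The protease Klk7, which sheds cells from the skin surface, fell (log2 ratios of -3.71 on array 1 and -6.50 on array 2), the tight junction gene Cldn4 fell by 3.39 ± 0.81 on the log2 scale, and the basal laminin gene Lamb3 rose 3.03-fold. Of 13739 genes tested, 4537 rose and 3887 fell by limma with Benjamini-Hochberg adjustment. At least 2-fold on both arrays, 206 genes were higher and 440 were lower. Without array 1, when 2-fold on array 2 alone suffices, the count of 2-fold higher genes was 338. The log2 ratios of the arrays correlated across genes with Pearson's r = 0.960 and Spearman's rho = 0.948, where genes are not independent replicates, and 89.3% of genes had the same sign on both. The split into 4537 and 3887 depends on the loess centring: centring each array on its median alone, which lifted the median of all tested genes by 0.53, gave 10281 higher and 988 lower, and lowering each array by its spike-in mean gave 288 higher and 12513 lower.

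**Figure D1:**
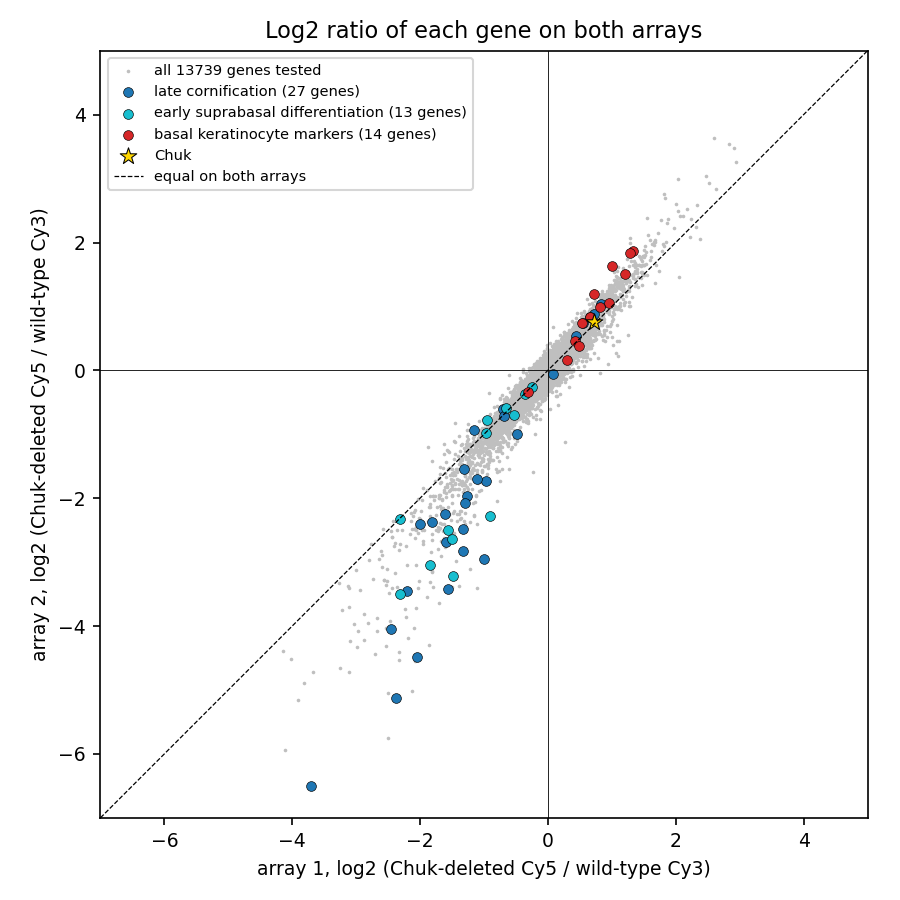
Each point is a gene, with its log2 ratio (Cy5, labelled Chuk-deleted, over Cy3, wild type) on array 1 on the x axis and on array 2 on the y axis. Coloured points are the tested members of 3 gene lists, the star is Chuk and the dashed line marks equal values. The late cornification and early suprabasal genes reach further below 0 on array 2, while 13 of 14 basal genes lie above 0 on both arrays.

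Early suprabasal genes, which keratinocytes switch on as they leave the basal layer, all fell: 13 of 13 tested members, with a median log2 ratio of -1.59 (-0.96 on array 1 and -2.27 on array 2). Tgm1, the transglutaminase that crosslinks the cornified envelope, fell by 2.90 ± 0.84, and so did Krtdap (-2.44 ± 0.85) and the transcription factor gene Ovol1 (-2.35 ± 1.23, and -1.49 on array 1). The desmosomal cadherin Dsg1a fell at least 4.02-fold (adjusted p = 8.17e-06, limma), as its Cy5 signal was not well above background on either array. Of the suprabasal keratin genes, named after their values were seen, Krt10 lay at -0.25 on each array (adjusted p = 0.00603, limma) and Krt1 fell at least 1.29-fold (adjusted p = 0.00122), with Cy5 again not well above background. Of 27 late cornification genes tested, 22 fell and 4 rose, with a median of -1.68 (-1.29 on array 1 and -2.08 on array 2). Besides Klk7 (-5.10 ± 1.97), the largest falls were those of Asprv1, the protease that processes profilaggrin (-3.75 ± 1.95, and -2.38 on array 1), Crct1 (-3.27 ± 1.73, and -2.05 on array 1) and Cnfn (-3.25 ± 1.12). The envelope protein genes Lor (-2.82 ± 0.89) and Flg (-2.14 ± 0.77) fell too. The 4 genes that rose were Lce1g, Lce1h, Lce1i and Tgm5, led by Lce1g at 0.94 ± 0.15. Of 11 small proline-rich genes tested, which encode envelope proteins, 9 fell and 0 rose, with a median of -1.25. Among them were Sprr2d (-3.36 ± 1.47), Sprr2h (-2.25 ± 1.63, and -1.10 on array 1), Sprr1a (-2.16 ± 1.34, and -1.21 on array 1) and Sprr2f (-2.52 ± 0.07), the last with Cy5 well above background on 1 of the 2 arrays. These 3 lists passed camera's threshold at the preset correlation (adjusted p = 1.26e-05, 0.000107 and 0.00202). None did so with an estimated correlation (adjusted p = 0.698 for each), where the test has 1 residual degree of freedom. On the same arrays melanocyte markers had a median of -0.86 and fibroblast markers one of 0.77.

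Desmosome and junction genes fell in 23 of 26 tested members and rose in 1, Gjb5 (0.79 ± 0.15), with a median of -0.76 (-0.08 with median centring alone, which lifted the median of all genes by 0.53). The largest falls were those of the claudins Cldn7 (-3.44 ± 1.56), Cldn4 (-3.39 ± 0.81) and Cldn1 (-2.60 ± 1.13), which seal tight junctions, and of the gap junction gene Gjb6 (-3.30 ± 0.04). Of 18 barrier lipid genes tested, 13 fell and 2 rose (13 and 3 when adjusted over the list alone), with a median of -0.53. They were led by Elovl4, which makes very long chain fatty acids (-2.93 ± 0.50), the lamellar body transporter gene Abca12 (-2.34 ± 0.38), the ceramidase gene Acer1 (-2.16 ± 0.23) and Elovl7 (-2.08 ± 0.36). The genes that rose were Smpd3 and Cers4. The lipid list's median was 0.04 with median centring alone. Camera gave adjusted p = 5.53e-06 for the junction list and 0.00202 for the lipid list at the preset correlation. Neither passed with an estimated correlation (adjusted p = 0.698 for each), where the test has 1 residual degree of freedom.

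Basal keratinocyte markers rose in 13 of 14 tested members, with a median of 0.83 (0.70 on array 1 and 0.92 on array 2, and 0.07 after lowering by the spike-in mean). The highest were Lamb3 (1.60 ± 0.38), Itgb4 (1.57 ± 0.39), Col17a1 (1.36 ± 0.22) and Lama3 (1.32 ± 0.44), which encode parts of the hemidesmosome and of the basement membrane laminin it binds. The basal keratin genes Krt14 and Krt5 rose by 0.43 ± 0.07 and 0.23 ± 0.10 (-0.33 and -0.52 after lowering by the spike-in mean), and Krt15 fell by 0.32 ± 0.02. Camera's adjusted p was 0.000286 at the preset correlation. The list did not pass with an estimated correlation (adjusted p = 0.698), where the test has 1 residual degree of freedom.

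Fibroblast markers rose in 15 of 18 tested members and fell in 2 (16 and 2 when adjusted over the list alone), with a median of 0.77 (0.01 after lowering by the spike-in mean). Fbln2 (1.84 ± 0.38), Sparc (1.55 ± 0.43), Fbn1 (1.27 ± 0.26) and Thy1 (1.11 ± 0.21) rose most, and the 2 that fell were Dcn (-0.60 ± 0.03) and Cd34 (-0.64 ± 0.04). Mesenchymal transition genes rose in 13 of 14 tested members, with a median of 0.51 (-0.24 after lowering by the spike-in mean, which lowered the median of all genes by 0.76). S100a4 rose by 1.33 ± 0.11, the fibronectin gene Fn1 by 0.96 ± 0.19 and the cadherin gene Cdh11 by 0.84 ± 0.09, while the transcription factor gene Foxc2 fell by 1.13 ± 0.03. Of 17 genes of matrix metalloproteases and the plasminogen system, 11 rose and 2 fell, with a median of 0.25 (-0.50 after lowering by the spike-in mean). Mmp10 rose by 0.81 ± 0.14, while Serpinb2 (-2.99 ± 1.06) and the metalloprotease inhibitor gene Timp3 (-1.72 ± 0.79) fell. Camera gave adjusted p = 0.000286, 0.00124 and 0.0218 for the fibroblast, mesenchymal and protease lists at the preset correlation. None passed with an estimated correlation (adjusted p = 0.731, 0.731 and 0.698), where the test has 1 residual degree of freedom.

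Melanocyte markers fell in 8 of 9 tested members and rose in 0, with a median of -0.86. The melanosome genes Mlana (-1.70 ± 0.24), Pmel (-1.49 ± 0.31), Dct (-1.43 ± 0.05) and Slc24a5 (-0.89 ± 0.05) fell most. Interferon-stimulated genes fell in 12 of 20 tested members and rose in 2, Stat2 and Psmb9 (13 and 2 when adjusted over the list alone), with a median of -0.26 (0.06 with median centring alone). The guanylate-binding protein gene Gbp3 (-1.55 ± 0.01), the RNA sensor gene Ifih1 (-1.02 ± 0.09) and the ubiquitin-like Isg15 (-0.77 ± 0.12) were among them. Rsad2 fell at least 1.88-fold (adjusted p = 5.19e-05, limma), with Cy5 not well above background on either array. Heat shock genes fell in 6 of 11 tested members and rose in 0, with a median of -0.39 (0.34 with median centring alone, and -0.19 without a call once the median of all genes is that under loess), led by the chaperone genes Hspa1a (-1.48 ± 0.57), Hspa1b (-1.40 ± 0.29) and Hsp90aa1 (-0.74 ± 0.08) and by Hsph1 (-0.65 ± 0.01). Of 27 G1/S and DNA replication genes, 13 fell and 3 rose, with a median of -0.14 (0.50 with median centring alone, and -0.02 once the median of all genes is brought back to that under loess). Mcm3, of the replicative helicase, fell by 0.51 ± 0.10 and the cyclin gene Ccne2 by 0.39 ± 0.06, Ccne1 lay at -0.44 and -0.43 on the arrays, and E2f1 (0.52 ± 0.13), Rrm2 and Uhrf1 rose. Camera's adjusted p was 0.000777 for the melanocyte, 0.000878 for the interferon, 0.0244 for the heat shock and 0.0256 for the G1/S list. None of the 4 passed with an estimated correlation (adjusted p = 0.698 for each), where the test has 1 residual degree of freedom. The interferon list did not pass there although its estimated correlation was -0.05, below the preset 0.01. That of the heat shock list was -0.02, while those of the melanocyte and G1/S lists were 0.22 and 0.08. Fry, which tests whether a list's genes move one way on balance, passed its threshold for the interferon list (adjusted p = 0.00295) and for no other. By rank among random lists, 12 of the 13 lists past camera's threshold passed too and the G1/S list did not (adjusted p = 0.0875). Random lists are drawn gene by gene, so this rank makes no allowance for correlation between genes either.

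**Figure D2:**
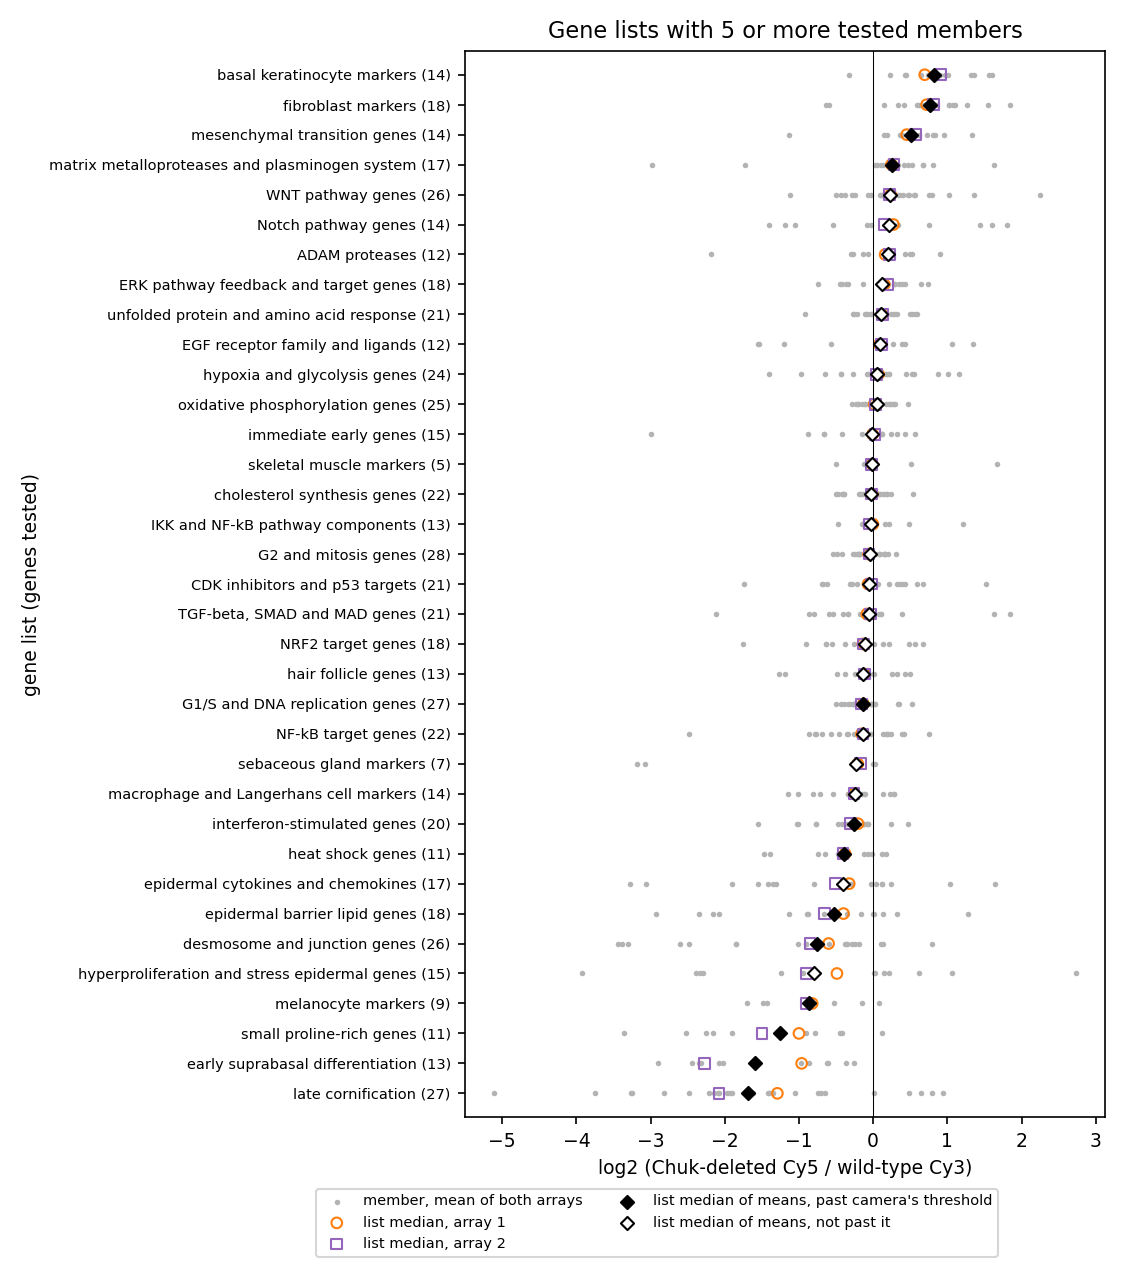
Each line is a gene list with at least 5 tested members (number tested in brackets). Grey points are members' mean log2 ratios (Cy5 labelled Chuk-deleted over Cy3 wild type), open circles and squares are the list's median on array 1 and array 2, and diamonds are the median of the means, filled where camera at the preset correlation passed its threshold. Medians run from -1.68 for late cornification to 0.83 for the basal markers.

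The remaining 22 tested lists did not pass camera's threshold (adjusted p from 0.0572 to 0.948). By the rank of their medians among 10000 random lists, 4 of them passed: stress keratinocyte and epidermal cytokine genes (adjusted p = 0.000636 for each, the smallest the random lists can give here), macrophage and Langerhans cell genes (adjusted p = 0.0125) and WNT pathway genes (adjusted p = 0.0294). Among EGF receptor family genes, 5 rose and 4 fell of 12 tested (median 0.10, mean -0.09). The rises were those of the ligand genes Epgn (1.35 ± 0.11), Nrg1 and Ereg and of the receptor genes Egfr (0.43 ± 0.10) and Erbb4, and the falls those of Erbb3 (-1.55 ± 0.34) and of the ligand genes Btc (-1.54 ± 0.48, with Cy5 well above background on 1 array), Tgfa (-1.20 ± 0.56) and Areg. Of 12 ADAM proteases, 7 rose and 3 fell (7 and 4 when adjusted over the list alone, median 0.20). Adam19 rose by 0.90 ± 0.14, Adam23 by 0.53 ± 0.08 and Adamts1 by 0.50 ± 0.05, while Adam8 (-2.19 ± 0.82), Adam10 and Adamts4 fell. ERK feedback and target genes rose in 9 and fell in 5 of 18 (median 0.12, and 0.15 on array 1 and 0.19 on array 2), with Dusp6 at 0.74 ± 0.10, Etv1 at 0.64 ± 0.04, Ier3 at -0.75 ± 0.31 and Epha2 at -0.45 ± 0.07, and Ccnd1, Myc and Epha4 also falling. Of 22 NF-kB target genes, 11 fell and 7 rose (median -0.14), and the chemokine genes Cxcl10 (-2.48 ± 0.38), Ccl5 (-0.87 ± 0.16) and Ccl2 (-0.79 ± 0.22) and the adaptor gene Traf1 (-0.77 ± 0.01) fell most. Among 13 components of the IKK and NF-kB pathway, 4 rose and 2 fell (3 and 1 when adjusted over the list alone, median -0.03, mean 0.07, and -0.0029 on array 1 and -0.058 on array 2). Map3k14, the gene of the kinase NIK that acts on IKKα, rose by 1.21 ± 0.21, Ikbke by 0.48 ± 0.07 and Ikbkb by 0.22 ± 0.07, with Traf2, while Rela fell by 0.47 ± 0.04, with Tbk1. Of 21 TGF-beta, SMAD and MAD genes, 9 fell and 3 rose (median -0.06, and -0.08 on array 1 and -0.03 on array 2). Mxd1, a MYC antagonist of differentiating cells, fell by 2.12 ± 0.71 and Tgfb2 by 0.87 ± 0.04, and the rises included Tgfbi (1.84 ± 0.24) and Tgfb1.

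Stress keratinocyte genes fell in 8 and rose in 4 of 15 tested members (median -0.79, and -0.49 on array 1). The beta-defensin gene Defb14 (-3.92 ± 1.14), the wound keratin gene Krt16 (-2.39 ± 1.40, and -1.39 on array 1) and Slpi (-2.34 ± 0.71) fell, as did S100a9 (-2.29 ± 0.27). The cystatin Stfa3 (2.73 ± 0.15), S100a8, Tnc and S100a7a rose. Epidermal cytokine genes fell in 10 and rose in 3 of 17 (median -0.40), with Csf2 (-3.27 ± 0.85), Pthlh (-3.06 ± 1.37) and Il18 (-1.90 ± 0.07) lower and Csf3 (1.64 ± 0.20), Cxcl14 and Il24 higher. Notch pathway genes rose in 8 and fell in 4 of 14 (median 0.22, and 0.27 on array 1 and 0.14 on array 2): the ligand genes Jag2 (1.80 ± 0.25), Dll1 (1.61 ± 0.09) and Jag1 (1.44 ± 0.11) rose, and the falls included Notch3, Nrarp and Hes1. Of 26 WNT pathway genes, 14 rose and 6 fell (15 and 6 when adjusted over the list alone, median 0.23), led by Wnt3a (2.24 ± 0.25), Dkk3 (1.36 ± 0.18) and Wnt3 (1.02 ± 0.17), with Wnt7b at -1.13 ± 0.38. Of 21 CDK inhibitors and p53 targets, 8 rose and 7 fell (median -0.05, and -0.07 on array 1 and -0.03 on array 2), among them Trp73 (1.52 ± 0.22), Cdkn2a (0.68 on each array), Gadd45b (-1.74 ± 0.33) and Cdkn2c (-0.69 ± 0.14). G2 and mitosis genes fell in 10 and rose in 5 of 28 (median -0.04), and the falls were small, with Nek2 at -0.54 ± 0.07, Cdk1 at -0.49 ± 0.03 and Nusap1 at -0.43 ± 0.02, while Cenpf (0.30 ± 0.11), Kif23, Ccna2, Mki67 and Cdc20 rose. Hair follicle genes rose in 4 and fell in 5 of 13 (4 and 7 when adjusted over the list alone, median -0.13). Sox9 lay at -1.27 on both arrays and Lef1 at 0.50, Tchh fell by 1.19 ± 0.05 and Gata3 by 0.49 ± 0.11, Padi3 and Krtap3-1 also fell, and Foxn1, Lgr5 and Lhx2 rose.

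Cholesterol synthesis genes rose in 5 and fell in 8 of 22 (median -0.03, and -0.0089 on array 1), with Dhcr7 at -0.50 ± 0.06, Cyp51 at -0.41 ± 0.21 (-0.27 on array 1) and Stard4 at 0.53 ± 0.11 (-0.095 as the mean over its probes), and other rises in Hsd17b7 and Nsdhl among them. NRF2 targets rose in 4 and fell in 7 of 18 (median -0.12), with Gsta4 at -1.76 ± 0.66, Hmox1 at -0.90 ± 0.28, G6pdx at -0.63 ± 0.08 and Gsta3 at 0.67 ± 0.06, and the other rises in Gclc, Nqo1 and Txn1. Hypoxia and glycolysis genes rose in 10 and fell in 6 of 24 (11 and 6 when adjusted over the list alone, median 0.05), with the glucose transporter gene Slc2a1 at 1.16 ± 0.24, Car12 at 1.01 ± 0.14, Ndrg1 at -1.41 ± 0.26 and Aldoc at -0.97 ± 0.26. Oxidative phosphorylation genes rose in 7 and fell in 5 of 25 (7 and 3 when adjusted over the list alone, median 0.05, and 0.014 on array 1 and 0.028 on array 2), with Ndufa1 at 0.47 ± 0.09, Cox7b at 0.29 ± 0.04, Uqcrc1 at 0.29 ± 0.10 and Cox5a at -0.29 on each array (0.04 with median centring once the median of all genes is that under loess), and other falls in Ndufs1, Sdha and Uqcrfs1 among them. Genes of the unfolded protein and amino acid response rose in 10 and fell in 4 of 21 (median 0.11), with Hsp90b1 at 0.59 ± 0.16, Slc7a5 at 0.56 ± 0.14, Pdia6 at 0.53 ± 0.06 and Dnajb9 at -0.92 ± 0.04, and the other falls in Atf4, Herpud1 and Xbp1. Immediate early genes rose in 4 and fell in 5 of 15 (median -0.01, and -0.0081 on array 1 and 0.023 on array 2, where the sign changes), with Egr2 at -3.00 ± 0.37, Atf3 at -0.88 ± 0.24, Klf4 at -0.66 ± 0.02 and Jund at -0.66 ± 0.09. Zfp36 fell too, and Egr1, Klf2, Btg2 and Jun rose.

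Among markers of other cell types, macrophage and Langerhans cell genes rose in 3 and fell in 7 of 14 (3 and 8 when adjusted over the list alone, median -0.24), with Lyz2 at -1.02 ± 0.08, Fcgr3 at -0.72 ± 0.11, and Adgre1 (-1.15 ± 0.17) and Csf1r (-0.81 ± 0.02) well above background in Cy5 on 1 array. H2-Ab1, H2-Eb1 and Aif1 rose. Sebaceous gland genes fell in 5 and rose in 0 of 7 (median -0.23), with Cidea at -3.19 ± 1.42 and Krt79 at -3.08 ± 1.73 (-1.86 on array 1), Mogat1 at -0.25 ± 0.11 and Pparg at -0.23 ± 0.03, and Plin2 also lower. Skeletal muscle genes rose in 2 and fell in 1 of 5 (median -0.02, mean 0.31), with Acta1 at 1.67 ± 0.56, Tnni2 at 0.51 ± 0.12 and Mylpf at -0.51 on array 1 and -0.50 on array 2. The other 5 lists had fewer than 5 tested members and no list test. Of 4 endothelial genes, Egfl7 (1.04 ± 0.21), Eng and Kdr rose and Flt1 fell (-1.86 on array 1 and -2.14 on array 2). Of 3 T cell genes, Cd3e rose by 0.21 ± 0.11 (0.13 on array 2, and a mean of -0.20 with median centring once the median of all genes is that under loess) and Cd28 fell by 1.24 ± 0.06, each well above background in both channels on 1 array only. Both adipocyte genes tested rose, Lpl by 0.58 ± 0.11 and Fabp4 by 0.20 and 0.21 on the arrays. The red blood cell gene Hba-a1 lay at 0.10 ± 0.09 (adjusted p = 0.180, limma), and Xist, the sex-linked gene tested, rose by 0.61 ± 0.09. For every list with a single pair of counts, adjustment over the list alone gave that pair too.

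**Figure D3:**
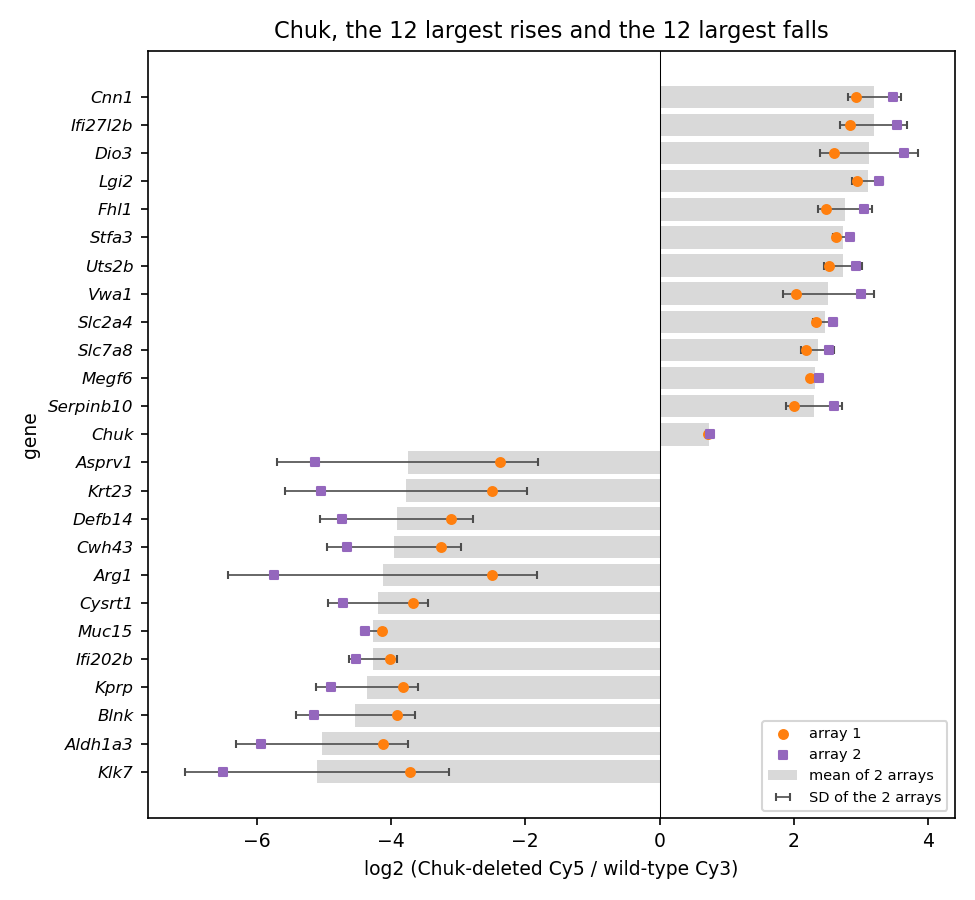
Bars are the mean log2 ratio (Cy5 labelled Chuk-deleted over Cy3 wild type) of Chuk, the 12 genes with the largest rise and the 12 with the largest fall, error bars the SD of the 2 arrays, and circles and squares the values on array 1 and array 2. The falls reach -5.10 and the rises reach 3.20.

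The 12 largest rises ran from Cnn1, which encodes an actin-binding protein of smooth muscle (3.20 ± 0.40, 9.17-fold), down to Serpinb10 (2.30 ± 0.42). Between them lay Ifi27l2b (3.19 ± 0.50), the thyroid hormone deiodinase gene Dio3 (3.12 ± 0.73), Lgi2 (2.94 on array 1 and 3.26 on array 2), the LIM domain gene Fhl1 (2.76 ± 0.40), Stfa3, Uts2b (2.73 ± 0.28), the matrix gene Vwa1 (2.51 ± 0.68), the insulin-regulated glucose transporter gene Slc2a4 (2.46 ± 0.18), the amino acid transporter gene Slc7a8 (2.35 ± 0.25) and Megf6 (2.31 ± 0.09). The 12 largest falls were led by Klk7 and by Aldh1a3, which makes retinoic acid (-5.03 ± 1.29, with -4.12 on array 1 and -5.94 on array 2). Then came the adaptor gene Blnk (-4.53 ± 0.88), the cornified envelope gene Kprp (-4.35 ± 0.76), Ifi202b, an interferon-inducible gene whose transcript differs between mouse strains (-4.27 ± 0.35), the mucin gene Muc15 (-4.26 ± 0.17), Cysrt1 (-4.19 ± 0.74), Arg1 (-4.12 ± 2.30), Cwh43 (-3.25 on array 1 and -4.66 on array 2), Defb14, Krt23 (-3.77 ± 1.80) and Asprv1. Without array 2, the falls of Arg1 and Krt23 were -2.50 and -2.50. Ifi27l2b, Cysrt1 and Cwh43 carried RIKEN clone names in the files and took their symbols from the reference table. The adjusted p of these 24 genes ran from 8.17e-06 to 0.00212 (limma with Benjamini-Hochberg adjustment).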

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

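Of the tests in this part, the comparison of the slopes of spike-in controls and genes was chosen after the result was seen. The 10 spike-in controls, RNAs added in set ratios to both labelling reactions, are not transcripts of the cells and entered no comparison. After loess their mean log2 ratio of Cy5 over Cy3 was 0.68 on array 1 and 0.83 on array 2, while the median of all genes tested was 0.02. They stand out because this signal in data outside the comparison lies far from the centre of the genes. The scanner software's own regression of observed on expected spike-in log ratios had slopes of 0.758 and 0.921 and intercepts of 0.75 and 0.97 on the log2 scale. Set against its own array's spike-in mean, the Chuk probe lay at 0.04 on array 1 and -0.08 on array 2. Loess holds the centre of the genes near 0, so the arrays alone do not say whether the RNA of one channel held less messenger RNA for its total or whether more spike-in was added to the Cy5 reaction. Neither was tested, and every value lowered by the spike-in mean carries that doubt.

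Log2 ratios were larger on array 2 than on array 1, with a slope of 1.19 over all genes tested. The spike-in controls had a slope of 1.18 (95% confidence limits 1.11 and 1.25), which is consistent with a compressed response of array 1 to any ratio. A single factor for all genes did not account for the late cornification genes: on array 2 they lay at a median of -0.42 after subtraction of the spike-in slope times their array 1 ratio, outside the range of -0.15 to 0.09 that held 95% of random lists matched on that ratio. In these genes the signal differed between arrays by 0.23 in Cy3 and by -0.63 in Cy5 (median log2, array 2 minus array 1). The design has no group that separates the arrays, so no biological explanation was tested, and a difference between replicate cultures in how far they had differentiated stays open.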

How the results depend on the processing

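Among these settings, scaling to the spike-in mean, limma's treat and median centring with the median set back to that under loess were chosen after the data were seen. Of 13739 genes tested, 4537 were higher and 3887 lower in the channel labelled Chuk-deleted, and both counts, the 2-fold counts of 206 and 440, the Chuk ratio and the count of 13 shifted lists stayed within 1.5 times and kept their direction with no background correction, normexp at offset 10, Aquantile, no filter or a stricter filter on dim probes, outlier spots kept and the mean over a gene's probes. The same 13 lists passed under these settings, except that the protease list lost its call with the mean over probes. The software's own log ratio gave 434 higher and 683 lower at 2-fold, and the values of the series' table gave 431 and 682. Median centring alone lifted the median of all genes by 0.53 and gave 10281 higher and 988 lower, with 1314 and 228 at 2-fold, so that 91.2% of calls were higher against 53.9% under loess. In absolute terms 17 of 169 named genes and 4 of the 13 lists changed sign there. With each array's median over all genes then set back to that under loess, the gene, 2-fold and list counts stayed within 1.5 times, and Cox5a lay at 0.038, Cd3e at -0.20 and Hba-a1 at -0.37. With the median over all probes set back instead, which left the genes' median 0.078 higher than under loess, 318 genes were at least 2-fold higher, the G1/S list lay at a median of 0.054, Cox5a at 0.12, Cd3e at -0.13 and Hba-a1 at -0.29. Lowering each array by its spike-in mean lowered the median by 0.76 and gave 288 higher and 12513 lower (2.25% higher), 29 and 2122 at 2-fold and a Chuk ratio of -0.018 (adjusted p = 0.881 by limma, against at most 0.00880 under the other settings with a test). It changed the sign of 26 named genes and 2 lists. Stard4 lay at -0.095 as a mean over its probes. Of the named genes, 5 lost the call with the software's ratio, 5 with the values of the series' table, 4 and 1 with median centring set back over probes and over genes, and 2 with the mean over probes.

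Stricter criteria call fewer genes by construction: 277 higher and 529 lower past the threshold and 2-fold in the mean, and 435 and 663 with treat against 1.5-fold. The software's p-value under 0.01 on each array, which comes from a different error model, gave 1242 higher and 1263 lower. At 1.5-fold on both arrays, 792 were higher and 935 lower. Of the 13 lists, 0 passed with camera at an estimated correlation and 1 with fry. At an estimated correlation camera has 1 residual degree of freedom, so that result does not decide whether the lists shifted. By rank among random lists 12 of them and 4 others passed, and the G1/S list did not. Median centring set back over genes, or over probes, kept 11 of the 13, without the G1/S and heat shock lists, and the spike-in mean kept 11, without the G1/S and protease lists. Median centring alone kept 10, without those 3. With 1 array left out, the 2-fold counts ranged from 227 to 338 higher and from 464 to 579 lower. These counts and their filter ask for 1 array only, so they are larger than the counts on both arrays largely by construction. Without array 1, 14 of 40 list medians moved by more than their spread, and 18 did without array 2. That spread is the SD of the same 2 arrays' medians, so these numbers do not measure how stable the lists are. The limma counts could not be recomputed with an array left out, as 1 array leaves no residual degrees of freedom. No further pairing could be added, because each log2 ratio already pairs the 2 RNAs of an array. The cause of the other changes was not tested. Signal over background limits what can be read: between 53.2% and 64.5% of gene spots were well above it per channel and array, and 158 called genes have only a bound in one channel.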

Other observations

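The grouping of genes by symbol, and the tests on basal genes and on exchanged channels, were chosen after results were seen; the other tests in this part were set before. Genes were grouped by the letters of their symbol ahead of the first digit, and of 229 groups with at least 8 tested genes 9 passed camera's threshold at the preset correlation. None passed with an estimated correlation (adjusted p = 0.993 for each), where the test has 1 residual degree of freedom. Collagen genes rose in 26 of 33 and fell in 1, Col9a3, in the channel labelled Chuk-deleted, with a median log2 ratio of 0.59 (adjusted p = 0.000169 at the preset correlation, and a median of -0.16 after lowering by the spike-in mean). The highest was Col7a1, which encodes the anchoring fibrils below the epidermis (2.08). The group includes Col1a1, Col1a2 and Col3a1 of fibroblasts, whose markers rose on the same arrays (median 0.77). Col7a1 was followed by the basement membrane gene Col4a1 (1.28) among those not on the lists. Integrin alpha genes rose in 10 of 11 and fell in 0, with a median of 0.64 (adjusted p = 0.00442, and a median of -0.12 after lowering by the spike-in mean), led by the collagen receptor gene Itga11 (1.08). Beta-protocadherin genes, adhesion molecules encoded in a cluster, rose in 11 of 13 and fell in 0, with a median of 0.30 (adjusted p = 0.0478, and -0.46 after lowering by the spike-in mean), up to 0.76 for Pcdhb21. With median centring alone their median was 0.35, below the median of 0.55 over all genes there, so this rise depended on the normalisation. The collagen and integrin alpha medians were 1.19 and 1.17 there.

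Keratin genes fell in 18 of 22, with a median of -0.86 (adjusted p = 0.00179 at the preset correlation), from Krt8 (-0.18) to Krt23 (-3.77). Of the basal keratin genes, Krt14 and Krt5 rose (-0.33 and -0.52 after lowering by the spike-in mean) and Krt15 fell (-0.32). Kallikrein genes fell in 6 of 8 and rose in 0 (median -1.62, adjusted p = 0.0328), with Klk10 (-1.83) and Klk11 (-0.60) beside the 4 of the cornification list. The small proline-rich group repeated its list (adjusted p = 0.0248). Falls were smaller in 3 more groups. Ubiquitin enzyme genes fell in 23 of 38 and rose in Ube2o (group median -0.21, adjusted p = 0.00442). Ube2o lay at -0.39 after lowering by the spike-in mean. Genes of translation initiation and of its regulators, such as Eif2ak2 and Eif4ebp1, fell in 26 of 51 and rose in 6 (median -0.15, adjusted p = 0.0328). Genes of the membrane-cutting Chmp proteins fell in 8 of 10 and rose in 0 (median -0.32, adjusted p = 0.0328). With median centring alone these 3 medians were 0.43, 0.56 and 0.32, against a median of 0.55 over all genes. The translation group was then no lower than the genes as a whole. With an estimated correlation each of these groups had adjusted p = 0.993.

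Differentiation genes were lower and basal keratinocyte genes higher in the channel labelled Chuk-deleted. Fewer keratinocytes there would lower basal genes too, and their median was 0.83 (0.07 after lowering by the spike-in mean). That rise is part of the pattern and was known when this test was chosen. It is therefore no independent evidence against fewer keratinocytes. Fibroblasts admixed in that channel would bring all their abundant transcripts, and of 6 checked, Sparc (1.55), Col1a2 (1.02), Col1a1 (0.84) and Col3a1 (0.62) were higher while Lum lay at 0.15 and Dcn at -0.60 ± 0.03. Median centring alone put Dcn at 0.03, or -0.50 once the median of all genes is that under loess, still the lowest of the 6. After lowering by the spike-in mean Sparc lay at 0.79, Col1a2 at 0.27 and Col1a1 at 0.09. Col3a1 (-0.14), Lum (-0.61) and Dcn (-1.35) lay below 0 there. None of the 20 fibroblast markers is on another list, and all 18 tested were well above background in the wild-type channel too. Loess had already centred genes of like intensity near 0, so a dye bias they all share was removed before this comparison. That 0% of 10000 random lists of like intensities had a median as low shows only that the early suprabasal genes lay below genes as bright. A block of differentiation that goes with the genotype is a candidate explanation, but a dye bias of single probes, fibroblasts of another kind in each culture and unequal culture conditions, which the labels do not give, stay open and untested.

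Chuk was higher in the channel labelled Chuk-deleted. Channels exchanged on 1 array would turn that array's ratios against the other's, but they correlated at 0.960 across genes. DNA of another strain around Chuk could set its neighbours apart. Of windows of 100 genes on each side, 21.3% had as high a median absolute log2 ratio as that around Chuk (0.23). Such a median hardly moves when DNA of another strain changes only a minority of the genes in a window. The test therefore does not decide the question, and DNA of another strain stays open. Channels exchanged in the labels of both arrays cannot be told apart from probes outside the deleted part by the Chuk ratio of 0.74, since neither the deleted part nor the probes' place is given. A dye bias of the Chuk probes stays open too, without a dye swap, and nothing measured here checks that Chuk was deleted. If the channels were exchanged, every direction given here would turn.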
